A study of Mus musculus with 2 samples.

How the data were processed

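MicroRNA libraries of mouse hippocampus were analysed, 2 in all, from wild-type females of the C57BL/6 substrain named B6NCrl in the labels. The labels call them biological replicates 1 and 2 of one control group. They have separate biosample records and a shared donor record, and no label says whether the tissue came from separate animals. The spread between these libraries may therefore be technical, and no p-value here measures a spread between animals. For single genes the exact test covers counting error only, and the other tests run across genes. The group is in the free-text descriptions, while the sex and age fields of the labels hold no value. These descriptions call the tissue layer of hippocampus and name no layer, so hippocampus below stands for that tissue. No second group exists, and every comparison is either among genes and gene lists or between the 2 libraries.

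Per the labels, RNA below 30 nt was sequenced after a multiplexed microRNA library protocol, and adapters were trimmed following a document that differs between the 2 libraries. Library preparation and biosample therefore cannot be separated. The authors deposited raw whole-number read counts per microRNA gene for the mm10 assembly and the GENCODE M21 annotation, per the notes deposited with each library. The aligner and counting program are not given in the sources used here. Each library has 3 count columns and 4 read classes: unmapped, mapped to several places, outside any microRNA gene, and ambiguous between genes. Within a library all columns sum to the same total, so reads that mapped to several places were given to no gene. The columns carry no heading. Their values identify them as counts without strand, on the strand of the gene and on the opposite strand. By a rule set before the data were examined, the strand-specific column with the larger total in both libraries, the sense column, was the main one.

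All 2202 gene identifiers matched microRNA genes of GENCODE M21, which gave symbols, coordinates, host genes and hairpin sequences. For each hairpin the longest stretch identical to a hairpin elsewhere was found, because a read inside such a stretch maps to several places. In all, 1135 genes shared 18 or more bases, and copies outside annotated microRNA genes were not searched. The read classes were left out of library sizes.

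Levels were CPM, each gene's sense counts scaled to a common total of sense counts over all microRNA genes, computed from the deposited counts and given as mean ± SD with n = 2. Replicate agreement used log2(CPM + 1) over the 466 genes with a mean of 10 or more counts, with 2000 bootstrap draws of genes for its interval. Dispersion was fitted in edgeR 4.0.16 with an intercept only. Ratios are log2 of replicate 2 over replicate 1 after adding 0.5 counts, scaled by edgeR's trimmed mean of M values (TMM), with a standard error that covers counting error only. For genes with 1 to 3 counts in a library the printed fold adds no counts and has an exact interval. A 2-sided Fisher exact test compared each gene's counts with all other counts, with Benjamini-Hochberg adjustment over the 466 genes at 0.05. It compares the 2 libraries, not conditions. A gene is called higher or lower only if it passed this test and its ratio had one sign under TMM, totals and DESeq2 1.42.0 size factors. For the most abundant genes the p-value lay below the smallest number the software represents, and is not printed. Median log2 ratios over all tested genes were -0.02 under TMM, -0.03 under DESeq2 size factors and -0.18 under totals.

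Genome clusters joined genes on one strand whose starts lay within 10 kb. The intraclass correlation over clusters of 2 or more tested genes was set against 100000 permutations of genes over clusters, 2-sided. Each marker list's median ratio was placed among 10000 random lists of the same size, drawn for each member from the 41 genes nearest in mean count. Exact Clopper-Pearson intervals have a 95% level, and a count of 0 was given a floor of 3 counts. Reads carry no molecular identifiers in these files, so intervals and floors cover counting error only.

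The 18 lists were fixed before the data were examined: let-7 family, neuron, activity-linked neuron, astrocyte, oligodendrocyte, microglia and blood leukocyte, endothelium, mural and smooth muscle, erythrocyte, choroid plexus and ciliated ependyma, Mir200 family, Mir183 cluster, Hox loci, muscle, liver with pancreas and gut, embryonic stem cell, imprinted Dlk1-Dio3 locus, and Mir17-92 with its relatives. Some genes are in more than 1 list. Named genes were the 20 with the highest mean CPM, up to 4 leading members of each list, and the 5 largest ratios each way among genes with a mean of 50 or more counts that passed the exact test. Others are marked as chosen after their values were seen.

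The steps were tested on simulated data. With 200 of 466 genes changed in Poisson counts drawn at the real depths, the exact test called 83.0% of the 100 genes changed 2-fold and 46.0% of the 100 changed 1.2-fold. It also called 16.2% of the 266 unchanged genes, because the changed genes altered the library totals, and it called 0 of 466 when no gene changed. A call therefore says that a gene's share of the library differed. The cluster statistic averaged 0.449 over 20 runs made with a correlation of 0.5, and -0.0108 over 20 runs made with 0. Values were drawn for 466 genes, and the 153 in clusters of 2 or more entered the statistic. The edgeR fit returned a coefficient of variation of 20.0% for a true 20% on 473 genes and 46.9% for a true 50% on 470 genes.

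The alternatives were the counts without strand, each library left out, TMM or DESeq2 scaling of levels, the most abundant gene left out of the total, genes sharing 18 bases left out, other count minimums, pseudocounts and cluster distances, a binomial test, and thinning of the deeper library. Further cluster alternatives, 3 in number, were added after seeing the data. Software was R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.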

Results

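The data were counts of microRNA reads from 2 libraries of wild-type female mouse tissue described as layer of hippocampus. The hippocampus is the brain region of memory formation. Replicate 1 held 15794475 reads, of which 6713867 were counted on the sense strand of microRNA genes, a share of 42.5% (exact 95% interval 42.5 to 42.5). Replicate 2 held 14300757 reads with 5901107 such counts, a share of 41.3% (exact 95% interval 41.2 to 41.3). Reads that mapped to several places made up 43.9% and 45.9%, unmapped reads 10.8% and 9.63%, and reads outside microRNA genes 2.78% and 3.17%. The mean share on microRNA genes was 41.9%. The labels name no contrast, so the libraries were described as a profile of the tissue and then compared with each other.

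A small set of microRNA genes supplied most of the counts. Mir139, in an intron of Pde2a on chromosome 7 (mm10, 101475376 to 101475443), had the highest mean level, at 137799 ± 71488 CPM (SD, n = 2). By mean level it was followed by Mirlet7b, Mirlet7i and Mirlet7g of the let-7 family, which marks differentiated cells, and by Mir127 of the imprinted Dlk1-Dio3 locus. This order also held in replicate 2, whereas in replicate 1 Mirlet7i (94910 CPM) and Mirlet7g (89071 CPM) exceeded Mir139 (87249 CPM), and Mir127 (79691 CPM) exceeded Mirlet7b (72727 CPM). The top gene held 13.8% ± 7.15 of the counts (SD, n = 2), the top 10 held 60.5% ± 5.56, the top 20 held 73.3% ± 3.49 and the top 50 held 89.3% ± 1.64. Of 2202 annotated genes, 293 reached 10 CPM in both libraries, 673 had a count in both, 787 in either and 1415 in neither.

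The other leading genes were spread over the genome. Mirlet7b lay in an exon of Lncppara on chromosome 15 (85707319 to 85707403) at 92258 ± 27622 CPM (SD, n = 2). Mirlet7i on chromosome 10 stood at 84347 ± 14938 CPM, Mirlet7g in an intron of Wdr82 at 74517 ± 20583 CPM, and Mir127 on chromosome 12 (109592846 to 109592915) at 64065 ± 22099 CPM. Mir744, in an intron of Map2k4, and Mirlet7d had means of 40247 and 39468 CPM. Below them came Mirlet7e, Mir23b, Mir125a, Mir770 in an exon of Meg3, Mir99a, Mir652, Mir132, Mir23a, Mir191, Mir149, Mir330, Mir324 and Mir99b. Mirlet7e, Mir125a and Mir99b are neighbours at Spaca6 on chromosome 17, between 17830188 and 17830879. Of the 20, Mirlet7b, Mirlet7i, Mirlet7g, Mir23a and Mir23b share 19 or 20 bases with another hairpin, so their levels leave out reads that fell within the shared part.

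**Figure D1:**
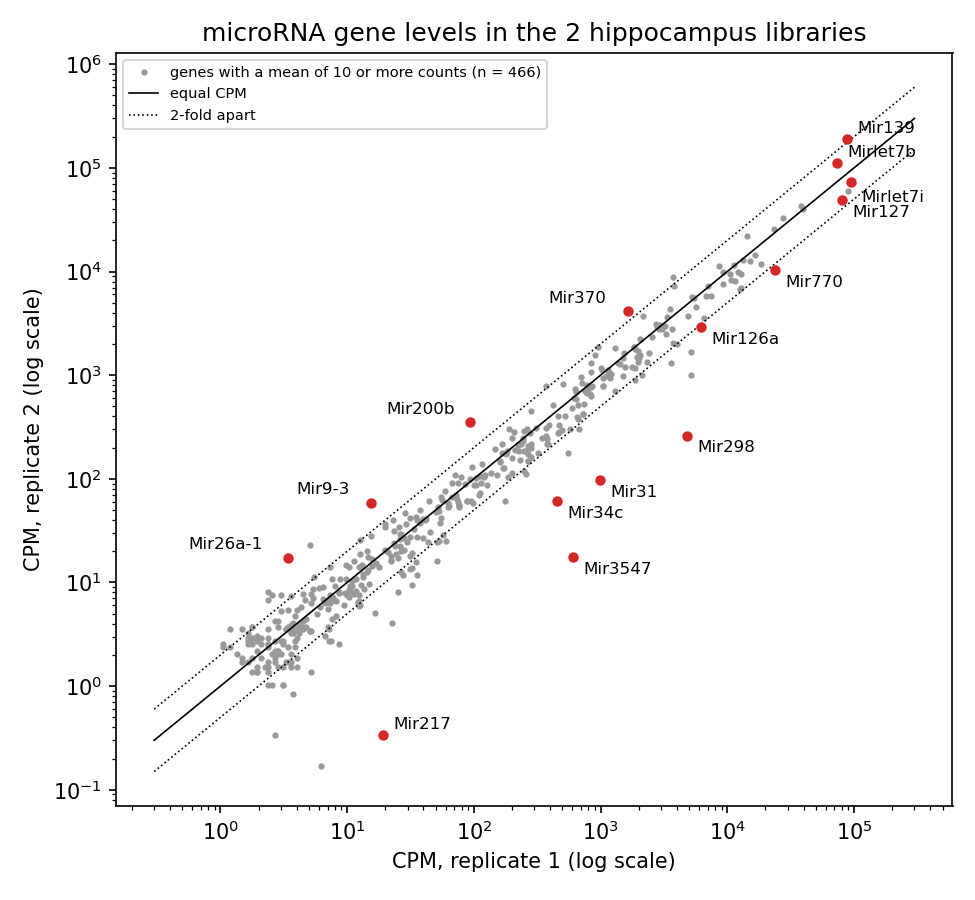
CPM of each microRNA gene in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale), for the 466 genes with a mean of 10 or more counts, with lines for equal CPM and for 2-fold differences. Red points are labelled genes, and Mir217, Mir298, Mir3547, Mir31 and Mir34c lie farthest below the line of equality among those with a mean of 50 or more counts.

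Among marker lists, the let-7 family was the largest, with all 12 members detected and 32.6% ± 0.378 of the counts (SD, n = 2). The imprinted Dlk1-Dio3 locus followed at 14.1% ± 4.12 (SD, n = 2), with 46 of its 55 members at a mean of 10 or more counts. The astrocyte list held 6.75% ± 0.402, led by Mir23b, Mir125a, Mir23a and Mir29a. The neuron list held 4.01% ± 0.0117, led by Mir132, Mir128-1, Mir383 and Mir138-2, and the list of microRNAs linked to neuronal activity, which contains Mir132, Mir485, Mir212 and Mir134, held 1.86% ± 0.216. The gaps between the let-7, Dlk1-Dio3, astrocyte and neuron lists exceeded their replicate SDs, though with 2 libraries no test between lists was made. The order of the leading pair turned without genes that share 18 or more bases, 9 of them in the let-7 list. The let-7 list then had 108124 CPM against 201817 CPM for the Dlk1-Dio3 list. That setting deletes Mirlet7b, Mirlet7i and Mirlet7g, at 92258, 84347 and 74517 CPM, but only 7 of 55 Dlk1-Dio3 genes. The turn follows from this deletion and does not show that shared sequence raised the let-7 level. Without genes that share 18 or more bases the astrocyte list had 42918 CPM and the neuron list 34053 CPM. Such genes made up 20 of 27 neuron members and 11 of 15 astrocyte members. Both sums leave out shared reads, so their order does not rank neuronal against astrocyte microRNAs in the tissue.

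Markers of oligodendrocytes, microglia, vessels and blood were present at lower levels than the astrocyte and neuron lists. The oligodendrocyte list, led by Mir219a-2 and Mir338, summed to 5135 ± 2748 CPM (SD, n = 2), and the endothelial list, which rests on Mir126a in an exon of Egfl7, to 4544 ± 2329 CPM. Both depend on strand-specific counts: they fell to 0.0797 and 0.962 CPM without strand, because Mir219a-2, Mir338 and Mir126a lie opposite other annotated microRNA genes. The Mir17-92 list had 2500 ± 163 CPM, led by Mir93, Mir92-1, Mir17 and Mir106b, the choroid plexus and ependyma list, led by Mir204, had 2313 ± 6.70 CPM, the microglia and leukocyte list, led by Mir150 and Mir146, had 2137 ± 154 CPM, and the mural list, led by Mir143 and Mir145a, had 1992 ± 690 CPM. In all, 11 of the 18 lists reached 1000 CPM.

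The remaining lists were low. The Mir200 family of epithelial cells, led by Mir200b, Mir429, Mir200c and Mir200a, had 482 ± 214 CPM (SD, n = 2), and the liver, pancreas and gut list, led by Mir375, Mir122, Mir194-2 and Mir217, had 478 ± 172 CPM. The Mir183 cluster, with Mir183 and Mir182, had 119 ± 32.8 CPM, and the erythrocyte list, with Mir451a and Mir486, had 52.9 ± 28.6 CPM, and 1.02 CPM without strand, since both genes lie opposite other microRNA genes. The muscle list, led by Mir206 and Mir499, had 30.8 ± 9.75 CPM and the Hox list, led by Mir10a, had 14.6 ± 11.6 CPM. The embryonic stem cell list had 1.98 ± 1.84 CPM, with Mir294 at 12 counts in replicate 1 and 0 in replicate 2, where 0 allows up to 0.508 CPM.

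**Figure D2:**
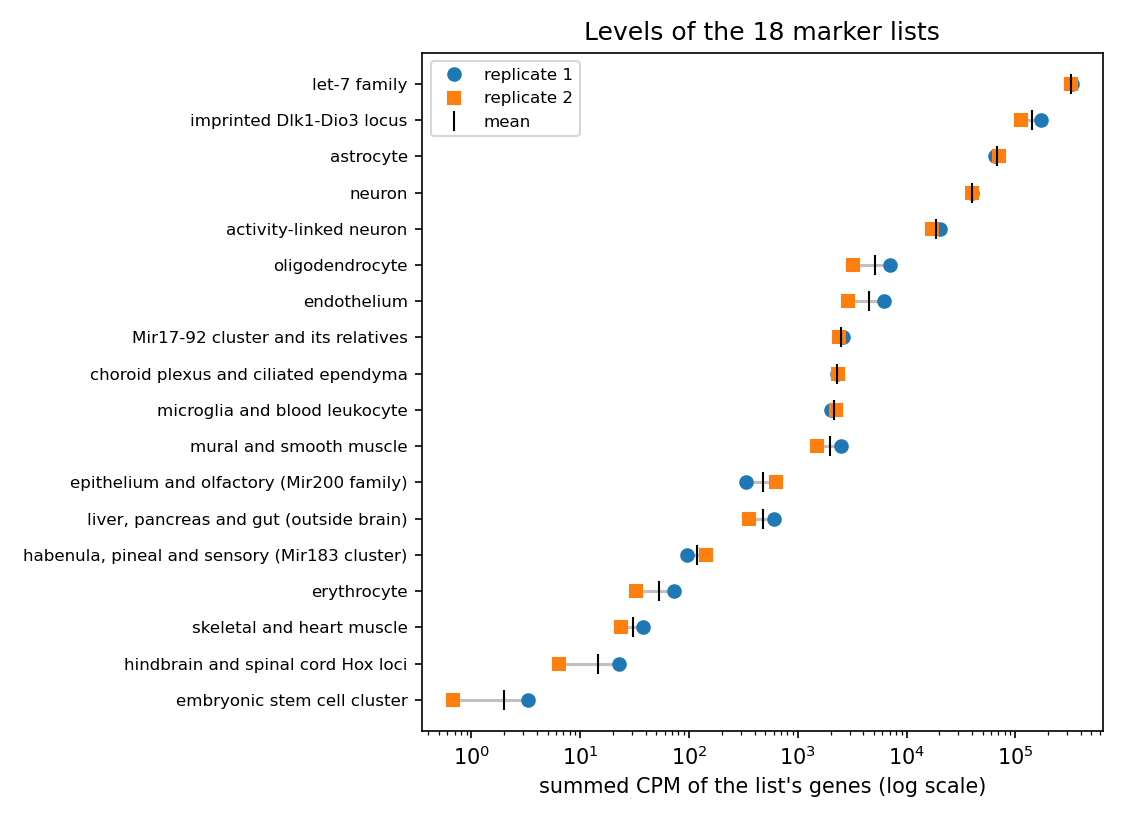
Summed CPM of the 18 marker lists (x axis, log scale) in replicate 1 (circles) and replicate 2 (squares), with the mean as a vertical tick. The let-7 family stands highest at 32.6% of the counts and the embryonic stem cell list lowest at 1.98 CPM.

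Several microRNAs with identical copies had few counts. Mir124a-1, Mir124a-2 and Mir124a-3, the copies of a microRNA widely used as a neuronal marker, had 8, 0 and 7 counts in replicate 1 and 5, 0 and 1 in replicate 2. Mir9-1, Mir9-2 and Mir9-3 had 299, 8 and 104 counts in replicate 1 and 362, 5 and 347 in replicate 2. Their hairpins share a stretch at least as long as a mature microRNA, and reads inside it are in the class that mapped to several places. Of the 1032 genes sharing 22 or more bases with another hairpin, 6.69% had a mean of 10 or more counts, against 33.9% of the other 1170. The counts of such genes, and of the lists that hold them, are therefore uncertain and leave out an unknown share of reads.

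Few reads lay on the strand taken as antisense, which is by rule the strand column with the smaller total. At the 2138 genes with no microRNA gene opposite, antisense counts were 190 in replicate 1 and 162 in replicate 2, shares of 0.00303% (exact 95% interval 0.00261 to 0.00349) and 0.00293% (exact 95% interval 0.00249 to 0.00342). Over all genes the shares were 6.12% and 5.88%, because 64 genes have a microRNA gene on the other strand. Mirlet7e and Mir191, among the 20 most abundant genes, had 0 counts in both libraries when strand was ignored.

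The 2 libraries ranked genes alike and differed in many levels. Across 466 genes Pearson's r of log2(CPM + 1) was 0.982 (bootstrap 95% interval 0.976 to 0.987) and Spearman's rho 0.972, genes not being independent replicates. Differences in log2(CPM + 1) had an SD of 0.72. Log2 ratios with 0.5 counts added had an SD of 0.82 and a median size of 0.36 under TMM, a 1.29-fold difference, and 404 genes (86.7%) lay within 2-fold. The common coefficient of variation fitted in edgeR was 34.2%. The libraries differed by more than counting error, with a chi-square per degree of freedom of 1385.

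Mir139, the gene with the highest mean level, took 8.72% of the counts in replicate 1 and 18.8% in replicate 2, a log2 ratio of 1.27 (counting SE 0.00233). By the Fisher exact test 268 of 466 genes (57.5%) differed between the libraries after Benjamini-Hochberg adjustment. Of these, 166 were lower and 84 higher in replicate 2 under 3 scalings. For 18, including Mir23a and Mir99b of the top 20, the sign depended on the scaling. Under TMM alone 166 were lower and 102 higher, so the rule of one sign removed only genes that were higher under TMM. The exact test also compares shares of the raw totals, and the median ratio over all tested genes was -0.02 under TMM. The excess of lower calls is therefore not a shift of all genes, and the same tilt enters the list counts below. Genes that passed and differed at least 2-fold numbered 53, of which 32 were lower and 21 higher in replicate 2 under TMM. Under totals they numbered 61, of which 45 were lower and 16 higher. The test covers counting error only, and a difference between 2 libraries has no replicate check.

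Among genes with a mean of 50 or more counts, those farthest lower in replicate 2 were Mir217, Mir3547, Mir298, Mir31 and Mir34c. Mir217, a microRNA of pancreatic acinar cells in an intron of Gm12082 on chromosome 11 (28763728 to 28763835), had 128 counts in replicate 1 and 2 in replicate 2, a ratio of 50.3-fold with no counts added (exact 95% interval 13.6 to 420). Mir3547, in an intron of Baiap3, had 4036 and 103 counts and Mir298, on chromosome 2 (174267504 to 174267585), had 32467 and 1542, with log2 ratios of -4.94 (SE 0.14) and -4.05 (SE 0.04). Mir31 had 6605 and 576 counts, a ratio of -3.17 (SE 0.06), and Mir34c, of multiciliated cells, 3028 and 361 counts, a ratio of -2.72 (SE 0.08).

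Under the same minimum of 50 counts, the genes farthest higher in replicate 2 were Mir26a-1, Mir301, Mir200b, Mir9-3 and Mir370. Mir26a-1 had 23 and 102 counts, a log2 ratio of 2.47 (SE 0.33), and Mir301, in an intron of Ska2, had 34 and 136, a ratio of 2.33 (SE 0.27). Mir200b, in an intron of Ttll10 on chromosome 4 (156055681 to 156055750), had 620 and 2064 counts and Mir9-3 had 104 and 347, each with a ratio of 2.08. Mir370, in an intron of Rian at the Dlk1-Dio3 locus, had 10987 and 24487 counts, a ratio of 1.50 (SE 0.02). Mir26a-1 and Mir9-3 share 25 and 26 bases with other hairpins, so their counts leave out shared reads.

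Median ratios of 3 lists lay outside the central 95% of random lists, the let-7 family, the Mir200 family and the Hox loci. Every list with tested genes was placed, with no adjustment for their number. Random lists draw each gene independently, whereas list members can share a cluster or sequence, so the percentiles can be too extreme. Of 12 let-7 genes, 8 were higher in replicate 2, 3 were lower and 1 did not pass, with a median log2 ratio of 0.40 (percentile 99.8) under TMM and 0.24 under totals. Their summed level went slightly the other way, 328821 CPM in replicate 1 and 323479 in replicate 2, because Mirlet7i and Mirlet7g were lower, at log2 ratios of -0.20 and -0.41. Of 5 Mir200 family genes, 4 were higher, Mir200b, Mir429, Mir200a and Mir141 (named after its value was seen), and Mir200c was lower, with a median of 1.18 (percentile 99.96). Mir429, Mir200a and Mir200b lie in the same cluster, and Mir141 and Mir200c in another, so these genes are not independent. Of 3 Hox genes, Mir10a and Mir10b were lower and Mir615 did not pass, with a median of -1.54 (percentile 0.700). Mir10a had 112 and 30 counts, and Mir10b 18 and 2, a ratio of 7.07-fold with no counts added (exact 95% interval 1.69 to 62.9). Adjusted over the list alone, 11 let-7, 5 Mir200 and 2 Hox genes passed, the same numbers as over all genes. Without genes that share 18 or more bases, 3 let-7 genes were left, with a median of 0.19 inside the central range (percentile 67.6). At a minimum mean of 50 counts the Hox list had 1 gene, Mir10a (percentile 5.70). With no filter on low counts the Hox median was -2.46 over 5 genes (percentile 0.065), the added genes having few counts.

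Lists of vessel, blood and myelin cells had medians inside the central 95% of random lists. Mir126a of endothelium was lower, at a log2 ratio of -0.93 (SE 0.01), as were Mir143 of mural cells at -0.64 (SE 0.02), and Mir451a and Mir486 of erythrocytes at -1.09 (SE 0.14) and -0.73 (SE 0.28). Of 6 leukocyte genes 4 were lower, including Mir146 at -0.63 and Mir155 at -0.36, and Mir150 and Mir146b (named after its value was seen) were higher, so that the summed level was 2028 CPM in replicate 1 and 2246 in replicate 2. Of 3 oligodendrocyte genes, Mir219a-2 was lower at -1.46 and Mir338 at -0.20, and Mir219a-1 did not pass. Mir145a, a neighbour of Mir143, had a ratio of 0.26 (SE 0.06) and did not pass. Median percentiles were 11.4 for endothelium, 41.0 for mural cells, 3.88 for erythrocytes, 4.61 for leukocytes and 34.3 for oligodendrocytes. With no filter on low counts the mural median went from -0.19 to -0.64 (percentile 14.6) and the oligodendrocyte median from -0.20 to -0.83 (percentile 4.08). Adjusted over the list alone, the counts that passed were 1, 1, 2, 6 and 2, as over all genes.

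Neuronal and astrocyte lists held genes lower and genes higher in replicate 2. Of 23 neuron genes 9 were lower and 8 higher in replicate 2, with Mir128-1 at a log2 ratio of 1.40 (SE 0.01) and Mir138-2 at -0.22 (SE 0.02), and the median was 0.02 under TMM and -0.14 under totals (percentile 53.8 for both) and -0.12 with no filter on low counts (percentile 22.9). Of 15 astrocyte genes 7 were lower and 4 higher, with Mir125a at 0.78 and Mir29a at -0.19, and the sign of the median depended on the setting. It was 0.11 under TMM and -0.05 under totals (percentile 84.4 for both), -0.07 without strand (percentile 46.8) and -0.62 for the 4 genes that share fewer than 18 bases (percentile 4.99). Of 7 activity-linked genes 3 were lower, among them Mir132 and Mir134, and 1 was higher (percentile 59.9). Adjusted over the list alone 19, 12 and 6 genes passed, including those whose sign depended on the scaling, the same numbers as over all genes.

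Of the other lists, choroid plexus and ependyma had 3 genes lower and 4 higher of 8, with Mir34c lower and Mir204 higher, at a log2 ratio of 0.27. Their median was -0.09 (percentile 46.5), and 0.27 (percentile 95.4) for the 7 genes with a mean of 50 or more counts. Mir183 and Mir182 were higher at 0.78 and 0.59 (percentile 95.4). In the liver, pancreas and gut list 5 of 6 genes were lower, with Mir375 at -0.58 and Mir122 at -0.23 (percentile 2.57). In muscle Mir206 was lower at -0.59, and Mir499 did not pass (percentile 22.1). Of 10 Mir17-92 genes 3 were lower, including Mir17 at -0.62, and Mir92-1 was higher at 0.48, with a median of 0.03 (percentile 63.3) under TMM and -0.13 under totals. Adjusted over the list alone 7, 2, 5, 1 and 5 genes passed, as over all genes, and no embryonic stem cell gene had enough counts to be tested.

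At the imprinted Dlk1-Dio3 locus on chromosome 12, where the maternal chromosome expresses a long array of microRNAs, 26 of 46 genes were lower in replicate 2 and 8 higher. Their median log2 ratio was -0.19 (percentile 9.02) under TMM and -0.35 under totals. The summed level was 170490 CPM in replicate 1 and 112209 CPM in replicate 2, and Mir127, at -0.56, and Mir770, at -1.04, carried most of that gap. Mir382 and Mir433 were lower, at -0.71 and -0.34, and Mir370, within the same locus, was higher. After adjustment over all genes 36 passed, and adjusted over the list alone 37 passed.

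**Figure D3:**
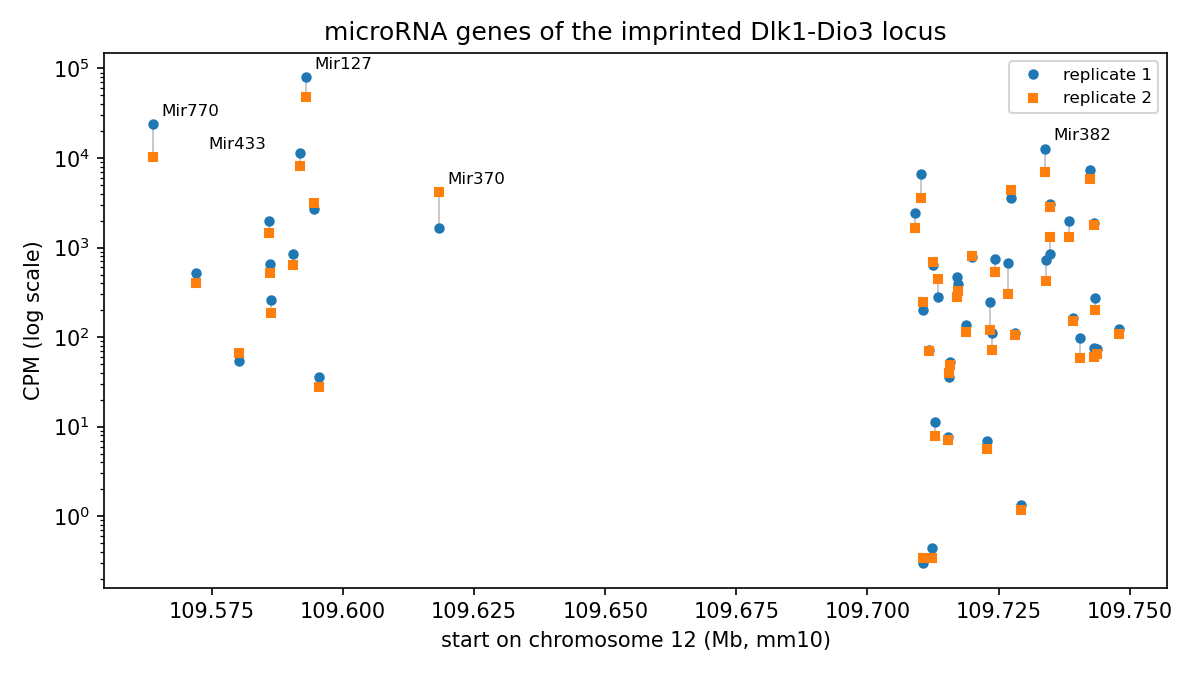
CPM (y axis, log scale) of the microRNA genes of the Dlk1-Dio3 locus against their start on chromosome 12 of mm10 (x axis, Mb), in replicate 1 (circles) and replicate 2 (squares), with a line joining the values of a gene. Mir127 and Mir770 were lower in replicate 2 and Mir370 was higher.

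Genes of one genome cluster resembled one another in level. Over 153 genes in 43 clusters the intraclass correlation of log2 CPM was 0.347 (permutation p = 1e-05, the smallest that 100000 permutations can give). It was 0.194 (permutation p = 0.0141) at a minimum mean of 50 counts and 0.528 (permutation p = 1e-05) without genes that share 18 or more bases. Within clusters levels still differed, as with Mir132 at 13806 CPM and its neighbour Mir212 at 731 CPM. The log2 ratios between the libraries had an intraclass correlation of 0.641 (permutation p = 1e-05, again the smallest possible). That value rested on a few clusters: it was 0.427 without Mir216a and Mir217, and 0.267 (permutation p = 0.00143) without these, Mir296 with Mir298, and Mir34b with Mir34c. On ranks it was 0.285 (permutation p = 0.00019). These last settings, and the genes Mir216a, Mir296 and Mir34b, were chosen after the values were seen.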

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

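Tests of the shared-copy explanation were chosen after the counts had been seen. Reads that mapped to several places are a signal outside the gene counts, and made up 43.9% of replicate 1 and 45.9% of replicate 2. Without strand, reads ambiguous between genes made up 2.77% of replicate 1 and 2.58% of replicate 2, against 0 in the sense column. Antisense counts at genes with no microRNA gene opposite were 0.00303% in replicate 1 and 0.00293% in replicate 2, in a column the comparisons did not use. They came from 56 genes, led by Mir3083 with 50 and 38 antisense counts beside 49 and 84 sense counts, a gene chosen after its values were seen.

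Mir124a and Mir9, neuronal microRNAs, held few counts. If reads shared between identical copies were the cause, genes with a copy of 22 or more bases should hold fewer counts than copy-free genes of their family. The copy-free gene was higher in 9 of 12 families in which a gene reached 10 CPM (exact 2-sided sign test, p = 0.146), among them Mir26b at 5480 CPM against 27.3 for Mir26a-2 and Mirlet7b at 92258 CPM against 1490 for Mirlet7f-2. Mir376b, Mir669c and Mir135a-2 went the other way. Copy-free here means fewer than 22 shared bases, and Mirlet7b shares 19. The sign test cannot decide the cause, because it compares different members of a family, which may differ in expression. The Mir124a and Mir9 families were also not among the 12, so the test does not bear on them directly. That reads inside a shared stretch were given to no gene follows from the count totals. How much of the low counts this loss accounts for is not known. Low expression of Mir124a and Mir9 in the tissue was not tested, and the reads that mapped to several places may hold their counts.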

How the results depend on the processing

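Some choices below were added after seeing the data: clusters without the Dlk1-Dio3 locus, without the 3 clusters of largest ratio, and on ranks. Among list medians outside the central 95% and cluster correlations, none changed sign. Calls for single genes were recomputed as counts, without following each gene. The number of detected genes, 293, was 441 with a minimum of 10 counts and 491 with 1 CPM, both less strict by construction, 301 to 315 from 1 library alone, 277 without strand and 219 without genes that share 18 bases. The share of reads on microRNA genes fell from 41.9% to 39.2% without strand, where genes on opposite strands are ambiguous. Replicate correlation was 0.988 with no filter and 0.973 with a minimum mean of 50 counts, and the cause was not tested. The antisense share was 0.00162% over genes with a mean of 50 or more counts. The share of the top 10 genes stayed within 1 SD under all 7 alternatives (57.5% to 64.5% from 1 library alone). With n = 2 a value from 1 library alone cannot pass 1 SD, and TMM or DESeq2 scaling cannot change the share of given genes. The informative alternatives gave 63.3% without strand, 56.3% without the most abundant gene and 59.5% without genes that share 18 bases. The number of lists at 1000 CPM was 9 to 11. Genes that differed numbered 201 to 268 under 7 alternatives, and those differing 2-fold 37 to 61, while the share lower in replicate 2 went from 61.9% to 68.7% under totals. The count of lists outside the central 95% was 2 to 4 against 3: the Hox list, left with 1 gene, dropped out at a minimum mean of 50 counts, the liver list came in without strand, and without genes that share 18 bases let-7 dropped out and the Mir183 cluster came in. Without genes that share 18 bases, the Dlk1-Dio3 list exceeded let-7, which follows from the deletion of the leading let-7 genes. Intraclass correlations over clusters stayed above 0 with a permutation p under 0.05 in all settings run, from 0.194 (minimum mean of 50 counts) to 0.528 for levels and from 0.267 to 0.726 for ratios, but the pair correlation of ratios without shared sequence was 0.0726 (permutation p = 0.339) without the 3 clusters of largest ratio. Of single list levels, 29 values moved by over 1 SD and 97 did not. With n = 2 a level from 1 library alone always lies within 1 SD of the mean, so those settings were bound not to move. Their values can still be far apart, as for the Hox list at 22.8 CPM in replicate 1 and 6.44 in replicate 2. The edgeR exact test was not run, since 1 library per side makes it void. Depth limits the Hox, muscle and stem cell lists, with few counts per gene.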

Other observations

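The tests on vessel markers, counting error and shared sequence were chosen after the ratios had been seen, and the cluster pair test before, except its forms on ranks and without 3 clusters. Of the 466 genes with a mean of 10 or more counts, 239 lay in introns of host genes, 114 in exons and 113 between genes. Chromosome 7, with Mir139, held 15.6% ± 6.95 of the counts (SD, n = 2), chromosome 12 held 14.7% ± 4.18 and the X chromosome 3.94% ± 1.15. Genes chosen after their values were seen included Mir34a, a target of the tumour suppressor p53, at 3586 CPM in replicate 1 and 1306 in replicate 2, and Mir107, in an intron of Pank1, at 5146 and 1005 CPM. Mir103-2 in Pank2 and Mir103-1 in Pank3, relatives of Mir107, were lower too, at 35.7 and 11.9 CPM and at 3.72 and 0.847 CPM. Mir26b, at 3766 and 7195 CPM, and Mir128-2, at 953 and 1882 CPM, were higher in replicate 2, as was Mir128-1.

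Ratios between the libraries exceeded counting error: 61.2% of 466 genes had an unadjusted exact p under 0.05, where counting error alone would give 5% or fewer. If the loci were transcribed differently in the 2 biosamples, genes of one cluster without shared sequence should deviate together, and their pair correlation was 0.716 (372 pairs, 203 of one sign, permutation p = 1e-05, the smallest possible). Most of these pairs came from the Dlk1-Dio3 locus. The pair correlation fell to 0.191 on ranks (permutation p = 0.0245). It was 0.0726 without the Mir216a, Mir296 and Mir34b clusters (permutation p = 0.339), which were left out for their large ratios. This explanation may therefore reach little beyond those clusters. The intraclass correlation without them, which includes genes of shared sequence, was still 0.267 (permutation p = 0.00143). If capture depended on the RNA sequence, genes at separate loci sharing 18 or more bases should deviate together, and their pair correlation was 0.560 over 42 pairs (permutation p = 0.00657) and 0.573 on ranks (permutation p = 0.00044), with 34 pairs of one sign. Reads wholly inside the shared stretch were given to no gene, so these ratios come from reads that reach outside it. The test is therefore indirect and does not measure capture of the shared stretch itself. Such pairs may also share transcriptional control, and the trimming documents differ between the libraries, so preparation and biosample stay open.

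Markers of vessel, blood and leukocyte cells were lower in replicate 2 in 8 of 11 genes (72.7%), a set pooled after the ratios were seen. Of the 455 other tested genes 50.1% were lower, a difference that did not pass a 2-sided Fisher exact test across genes (p = 0.221). A larger share of such cells in replicate 1 would lower Mir143 and Mir145a alike, since both are cut from one transcript, and their log2 ratios differed by 0.902. As the test was written, a gap over 0.5 counted against this explanation, and so did the share of markers that were not lower. Both criteria as written thus went against it, and the 95% counting interval of the gap was 0.774 to 1.03. The spreads that follow were not part of the test as written. Over all tested genes the log2 ratios had an SD of 0.82, so any 2 tested genes differ by up to 2.27 within the 95% spread. That spread does not show how far 2 products of one transcript can differ. Of 372 pairs of cluster neighbours 51, this pair included, lay as far apart as Mir143 and Mir145a, though the median gap was 0.41. Most of the 372 pairs came from the Dlk1-Dio3 locus, so they mainly describe that locus and not cluster neighbours in general. The share of markers lower rests on 11 genes, and its exact 95% interval reaches up to 94.0%. With these limits a larger share of vessel and blood cells stays open, and so does chance.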
